A study of Mus musculus with 8 samples.

How the data were processed

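Satellite cells were sorted from mouse skeletal muscle by flow cytometry, with integrin alpha 7 as the marker kept and CD31, CD45, CD11b and Sca1 as markers removed. Total RNA of each of 8 samples, 4 from basal muscle and 4 from muscle 3 days after cardiotoxin, was labelled with Cy3 per the labels and put on 1 array each of a mouse design with 62976 spots, of which 59305 per array are not controls. The labels call the samples biological replicates of male C57BL/6 mice aged 3 months and state no pooling of animals.

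The deposited scanner files hold spot signals in intensity units, which the authors made with Agilent Feature Extraction 10.7.3.1 per the file headers. The software subtracted background, detrended each array and marked spots that were saturated, uneven or not well above background, without normalization between arrays. The normalized values deposited by the authors, called the authors' deposited table here, come as 8 columns on a log2 scale with like distributions, with column medians of 8.05 to 8.16, a lowest value of 5.66 and a highest of 18.8. The labels name Agilent Feature Extraction and limma; which steps made the table, and the limma version, are not given in the sources used here. The log2 scale was read from the values. That table was used for an alternative only.

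The processed signal of each non-control spot was put on a log2 scale, and the 75th percentile of each array was subtracted. The 1119 spots marked as uneven or as population outliers were left out, and spots of the same probe were averaged (55681 probes, 399 of them spotted 10 times). Probes were named from the mouse reference gene table by accession (26300 probes), by array names that are current symbols (2044) or synonyms of 1 symbol (355), or by the array's own name (555). The other 26427 probes had no gene name. Each of 21750 genes was represented by its probe with the highest mean signal over the 8 arrays. The 13646 genes whose probe was well above background on at least 3 of the 4 arrays of at least 1 group were tested. Of these, 3426 genes had more than 1 probe that passed this filter, and 168 called genes had probes that were themselves called in opposite directions. Genes whose probes differed in call alone are not in that count. Probe positions are those of the array files, on the mouse genome build mm9. A value was missing for 9 genes, and lists were tested on genes without missing values.

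Injured and basal arrays were compared with limma 3.58.1 in R 4.3.3. Files were read with the R package data.table, version 1.17.8. The model was linear per gene with moderated variances, 6 residual and 2.55 prior degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Log2 differences are injured minus basal, errors are moderated standard errors with n = 4 per group unless an SD is named. Of the genes tested, 8809 had an unadjusted p under 0.05. A fixed set of 29 gene lists covered pathways and markers of other cell types. The 26 with at least 5 genes tested were tested with limma's camera, which sets a list against all other genes, with a preset correlation between genes of 0.01 and again with an estimated correlation. They were also tested with fry, which asks whether a list's genes move one way and compares them with no other genes. Calls for lists use camera with the preset correlation, adjusted over the lists. The counts adjusted over the list alone use the genes of 1 list as the family of tests. Values against a group not above background on any array are given as bounds, for 774 genes.

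The groups, the test, the gene lists, the alternatives and the genes that could be named were set before the data were examined. Named genes were the 10 with the largest rise and the 10 with the largest fall among called genes with a standard symbol and no overlap between groups, and 19 landmark genes of satellite cells and of the sort. For each list they were up to 4 called members with the largest difference in the direction of most called members and up to 2 in the other. Members that complete a count of 5 or fewer, sex-linked and imprinted genes, endothelial transcripts and genes of symbol families were chosen after their values were seen.

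The alternatives tried were quantile normalization, normexp background correction (offset 50) with quantile normalization or with the 75th percentile, scaling to the median of probes above background on all arrays, the authors' deposited table, no filter on dim probes, genes above background on all arrays, the mean of all probes of a gene, limma's trend and robust options, array weights, the replicate number as a block, and leaving out each array in turn. Chosen after seeing the data were the comparisons without basal replicates 1 and 2, without injured replicates 2, 3 and 4, and with probes that have no symbol. A slide block was planned and not run, since each of the 2 slides holds 1 group. The replicate number is the position on the slide, and deviations of same-numbered arrays from their group means correlated at -0.01 to 0.19 across genes, so arrays were not paired.

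The pipeline was tested on simulated data made from the arrays' own spread. It called 70.6% of genes lowered and 75.8% of genes raised by a log2 change of 2, 47.1% and 51.5% at a change of 1, and 6.06% and 0% at a change of 0.5. It called 1 of 13412 unchanged genes, and the 1 shifted list was called and 0 of 19 unchanged lists. The simulated values were independent between genes and the lists were random, so the list result does not cover lists with correlated members. Few genes were changed in the simulation, against 60.1% of the genes tested called in the data, so the shares called can differ there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.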

Results

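Gene expression was measured on 1-colour Agilent arrays in satellite cells, the resident stem cells of skeletal muscle, sorted from mice labelled as C57BL/6 males aged 3 months. Cells came from basal muscle (n = 4 arrays) or from muscle 3 days after injection of cardiotoxin, a snake venom toxin that destroys muscle fibres (n = 4 arrays). Each array held the RNA of 1 labelled biological replicate. Of 59305 non-control spots per array, 50.1% to 56.7% were well above background. No spot was saturated, and the 75th percentile of the processed signal was 104 to 132. Over 10673 genes above background on all arrays, Pearson's r across genes, which are not independent replicates, was 0.989 to 0.996 between injured arrays. It was 0.954 to 0.978 between basal arrays and 0.832 to 0.922 between an injured and a basal array. The comparison of injured with basal muscle asks which transcripts differ between satellite cells that the submitters call activated and quiescent. The number of arrays limits the precision of every value.

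After injury, satellite cells had lower signal for 24 of 26 genes of satellite cell quiescence, 23 of 25 of the immediate early response and 18 of 25 of the extracellular matrix, where 6 were higher. They had higher signal for 28 of 31 genes of DNA replication, 26 of 26 of mitosis and 31 of 31 of oxidative phosphorylation. The same held for 26 of 26 genes of the proteasome, 21 of 23 of ribosome biogenesis, 13 of 19 of glycolysis and 12 of 14 of the embryonic sarcomere. The tests of these lists passed with a preset correlation between genes, and none passed with an estimated correlation (adjusted p 0.326 to 0.410). Pax7, the transcription factor that marks satellite cells, fell by 2.95 ± 0.21 on the log2 scale (SE, n = 4 arrays per group; adjusted p = 1.8e-05) and was lower on all 4 injured arrays than on every basal array. Ccnb1, the cyclin that starts mitosis, rose by 4.47 ± 0.89 (adjusted p = 0.00267). Myog, the transcription factor of muscle differentiation, rose by 4.09 ± 0.71 (adjusted p = 0.00128), and both were higher on all 4 injured arrays than on every basal array. Both were above background on only 3 of the 4 basal arrays, so their sizes rest in part on dim values. Of 13646 genes tested, 4823 were higher and 3379 lower at an adjusted p under 0.05, and 5444 were not called. The log2 difference was 1 or more for 2790 of the higher genes and -1 or less for 1944 of the lower genes. The groups' values did not overlap for 7799 genes, or 57.2%, where chance gives 2.86%. All basal arrays shared 1 slide and scan date and all injured arrays another, so injury cannot be told apart from slide or scan. Injured 2, 3 and 4 had high signal of the female RNA Xist and no Y-linked gene above background, although all mice were labelled male. A difference in sex between the groups thus cannot be told apart from injury either.

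**Figure D1:**
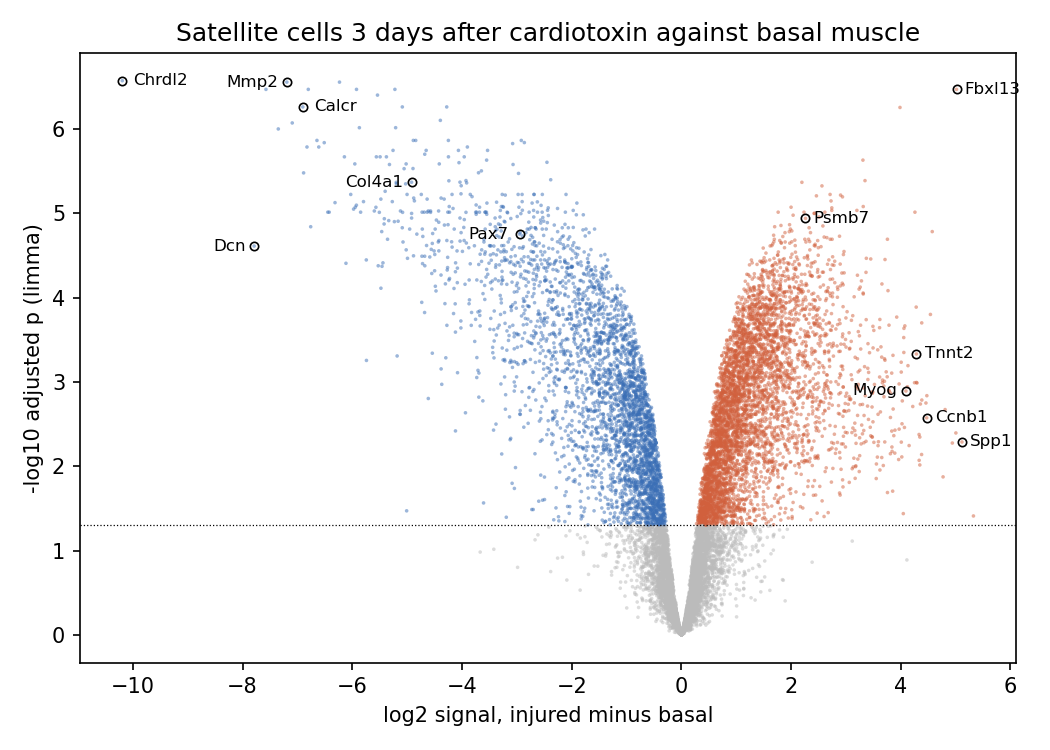
Each point is 1 of the genes tested, with the log2 signal of injured minus basal arrays on the horizontal axis and the negative log10 of the limma adjusted p on the vertical axis. Red points are the 4823 higher genes, blue points the 3379 lower genes, grey points genes not called, and the dotted line is an adjusted p of 0.05.

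Among genes whose groups did not overlap, the lower genes reached larger sizes than the higher ones with all arrays. The sizes of rises depended on basal 1 and basal 2. There, 120 genes at least 16-fold higher on injured arrays than on basal 3 and 4 had medians of 25.7% and 8.62% of their injured level. That signal raises their basal mean and makes their rises smaller. The 159 genes at least 16-fold lower kept medians of 63.1% and 87.4% of their basal level there. Chrdl2, a secreted antagonist of bone morphogenetic proteins, was at least 346-fold lower (probe on chromosome 7, 107183146 to 107183205, mm9; adjusted p = 2.7e-07), since it was not above background on any injured array. Dcn, a proteoglycan of the extracellular matrix, fell by 7.79 ± 0.59 on the log2 scale (probe on chromosome 10, 96980233 to 96980292; adjusted p = 2.4e-05). Mmp2, a gelatinase, was at least 104-fold lower (adjusted p = 2.8e-07), and Calcr, the calcitonin receptor carried by quiescent satellite cells, was at least 32.9-fold lower (adjusted p = 5.5e-07). Other genes at this end were Ttyh1, the imprinted non-coding RNA Meg3, the lectin Chodl, the sphingosine 1-phosphate receptor S1pr3 and the transcription factor Cebpd, which fell by 6.61 to 7.35. At the other end, Spp1, which encodes the matrix protein osteopontin, rose by 5.12 ± 1.17 (probe on chromosome 5, 104868502 to 104868561; adjusted p = 0.00516). Fbxl13, an F-box protein, was at least 9.35-fold higher (adjusted p = 3.4e-07). Cenph, a kinetochore protein, was at least 10.5-fold higher (adjusted p = 1.7e-05) and Mbnl3, a splicing regulator, at least 9.50-fold higher (adjusted p = 1.6e-04). None of these 3 genes was above background on any basal array. Trp53i11, the adhesion molecule Nrcam, the chromatin protein Hmga2, the embryonic myosin heavy chain Myh3 and the caveolar protein Cavin4 rose by 4.48 to 5.0. Hmga2 was above background on only 2 basal arrays, so its size rests in part on dim values. It lay at 0.58 and -1.39 on basal 1 and 2 and at -4.08 and -3.48 on basal 3 and 4. A lower bound on a fold sets the mean of the detected group against the other group, with each array of that other group at no less than its dimmest probe well above background.

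Among the other landmark genes, Spry1, an inhibitor of growth factor signalling, fell by 4.02 ± 0.21, the surface marker Cd34 by 2.85 ± 0.33, and the Notch target Hey1 by 2.41 ± 0.34 (adjusted p = 5.9e-06, 1.8e-04 and 4.3e-04). Myod1, the transcription factor of activated myoblasts, rose by 0.77 ± 0.13 (adjusted p = 9.7e-04) from a basal signal of 4.46 ± 0.14 (SD, n = 4). The proliferation marker Mki67 rose by 2.65 ± 0.42 (adjusted p = 8.2e-04). The cell cycle inhibitors went different ways, with Cdkn1b down by a log2 difference of -1.45 and Cdkn1c up by 2.26. Cdkn1a rose by 1.03 (adjusted p = 0.0254), but its probes differed in direction and their mean gave 0.16 (adjusted p = 0.555). Its adjusted p was 0.0564 without basal 3, 0.0695 without injured 3 and 0.0636 without injured 4. Of the genes behind the sort, Itga7, the integrin used for selection, rose by 1.13 ± 0.15. Its partner Itgb1 rose by 0.74 ± 0.16, a call lost with quantile normalization (0.41, adjusted p = 0.0646). Ptprc, which encodes CD45, differed by -0.18 (adjusted p = 0.698), by 0.13 without basal 4, and by -0.88 (adjusted p = 0.00906) without basal 1 and basal 2. Itgam, which encodes CD11b, differed by 0.10 (adjusted p = 0.491), though the call was made with normexp and quantile normalization (0.25, adjusted p = 0.0171). Its probe had a mean log2 signal of 8.82 on basal and 8.92 on injured arrays. The other Itgam probes lay far lower, at -0.26 and -0.32 and at -1.28 and -1.08. Which of these probes measures Itgam was not tested, so the value does not settle the level of CD11b RNA. Pecam1, which encodes CD31, differed by -2.38 ± 1.43 (adjusted p = 0.178), by -3.51 (adjusted p = 0.041) without basal 4 and by 0.49 (adjusted p = 0.363) without basal 1 and basal 2. It was called in the authors' deposited table (-2.78, adjusted p = 0.0123). Myf5, an early myogenic transcription factor, was not above background on any array, with its probe at -5.31 to -3.65. Whether that probe can detect Myf5 was not tested, so the value does not settle the level of Myf5 RNA. Ly6a, which encodes Sca1, was above background on 2 basal and 2 injured arrays and not tested. In the authors' deposited table, the calls of Hey1 (-1.04, adjusted p = 0.116), Cdkn1b (-0.62, adjusted p = 0.252) and Itgb1 (0.41, adjusted p = 0.269) were lost.

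**Figure D2:**
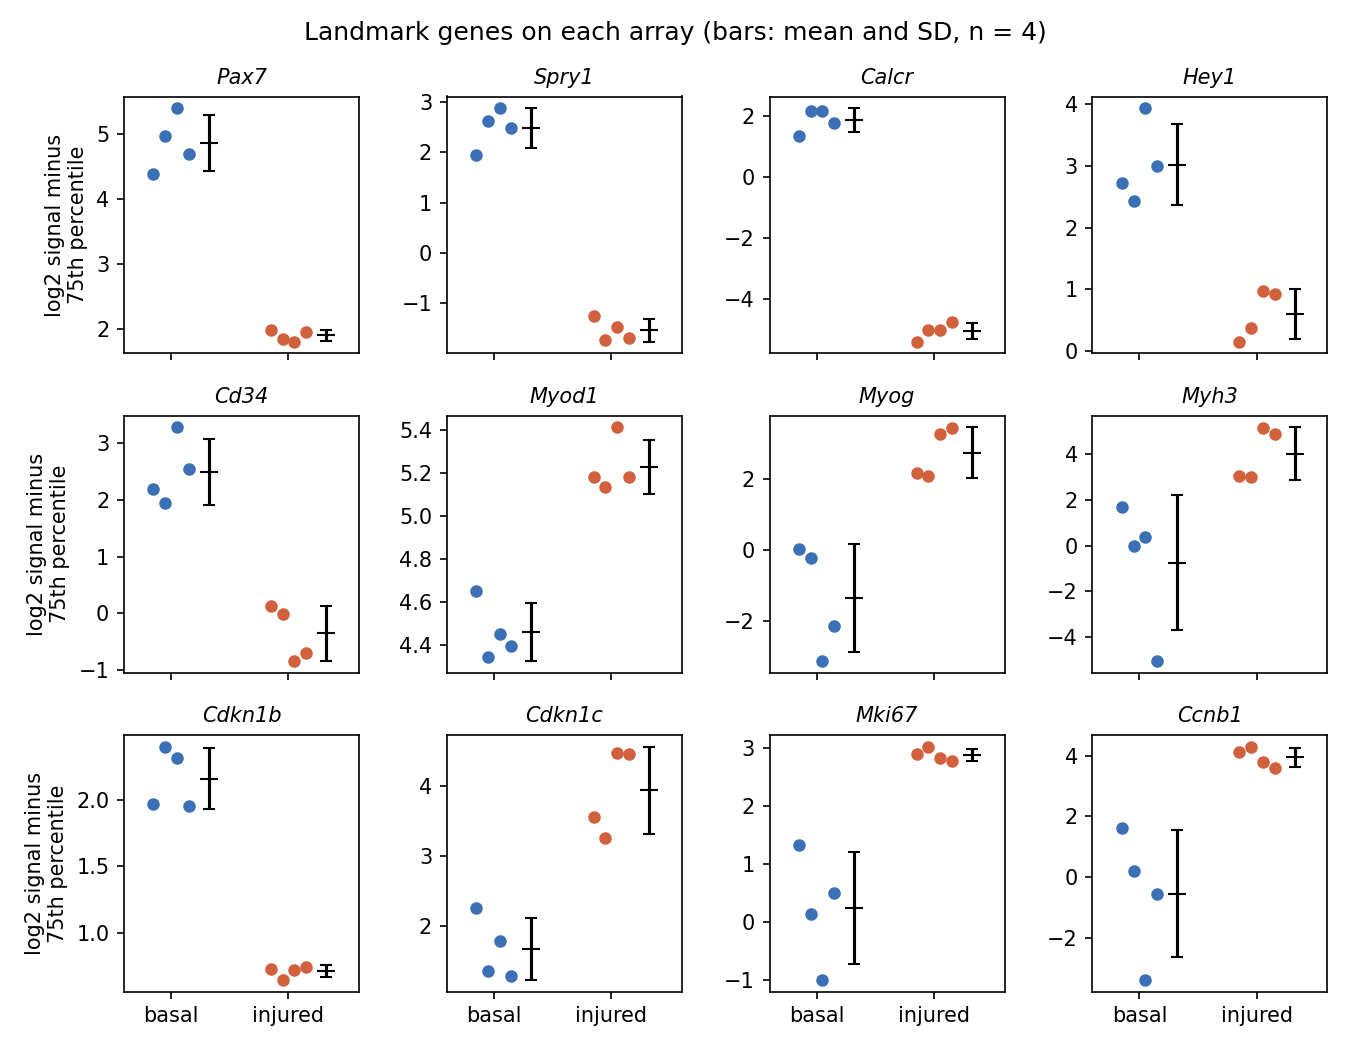
Each panel gives 1 landmark gene, with the log2 signal minus the array's 75th percentile on the vertical axis, 4 basal arrays in blue, 4 injured arrays in red, and bars for the mean and SD of each group. Pax7 lies at 4.86 ± 0.43 in basal and 1.91 ± 0.09 in injured arrays, and Myog at -1.35 ± 1.52 and 2.74 ± 0.71.

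Gene lists were fixed before the data were examined, and each count of higher and lower members is followed by the count adjusted over the list alone. The immediate early and dissociation stress list, genes induced within minutes by stimuli that include tissue dissociation, had 0 higher and 23 lower of 25 members tested (0 and 23 adjusted over the list alone). Its median log2 difference was -3.74 (camera adjusted p = 2.7e-13; adjusted p = 0.340 with an estimated correlation). Its members included Btg2, an antiproliferative gene, the transcription factors Cebpb and Atf3, and Zfp36, which speeds mRNA decay, which fell by 4.82 to 5.60. The satellite cell quiescence list had 1 higher and 24 lower of 26 (1 and 24 adjusted over the list alone). Its median was -3.05 (camera adjusted p = 9.2e-13; adjusted p = 0.326 with an estimated correlation). Besides Chrdl2 and Calcr, the growth factor Bmp6 fell by 5.42 ± 0.35 and the secreted peroxidase Gpx3 by 5.32 ± 0.25, while Cdkn1c was the 1 higher member. Of the 27 genes on this list, 10 are on another list, 5 of them among the 25 Notch pathway genes, so the lists are not independent. Of the extracellular matrix list, 6 were higher and 18 lower of 25 (6 and 18 adjusted over the list alone). Its median was -2.44, or -2.62 to -1.51 over the alternatives (camera adjusted p = 8.0e-06; adjusted p = 0.326 with an estimated correlation). The basement membrane collagen Col4a1 fell by 4.92 ± 0.25 and the proteoglycan Bgn by 4.14 ± 0.29, while Timp1, an inhibitor of matrix proteases, rose by 4.35 ± 1.13 beside Spp1. Of the 31 genes on this list, 4 are on another list, Dcn, Col1a1 and Col3a1 among the fibro-adipogenic progenitor genes and Col5a1 among those of quiescence. Of the pericyte and fibro-adipogenic progenitor lists, 7 of 12 and 7 of 13 members were lower as well, though neither list was called with an estimated correlation (adjusted p = 0.340 and 0.398). The Notch pathway list had 5 higher and 11 lower of 22 (5 and 11 adjusted over the list alone). Its median was -1.10, or -1.22 to -0.28 over the alternatives (camera adjusted p = 0.00993; adjusted p = 0.340 with an estimated correlation). The targets Hes1, at least 11.9-fold lower (adjusted p = 1.2e-04), and Heyl, down by a log2 difference of -4.19, fell with the ligand Jag1, at least 3.81-fold lower (adjusted p = 4.6e-05), and the ubiquitin ligase Dtx4 (-2.78). The higher members were Hes6 (1.88), which opposes Hes1, the ligands Jag2 (1.64) and Dll1 (0.96), the ligase Mib1 (0.68) and the glycosyltransferase Rfng (0.45). Jag2 was called only with basal 1 or basal 2 left out or with all arrays (adjusted p 0.0644 to 0.0987 without any of the others). Dll1 was not called without injured 3 (adjusted p = 0.0511) and Rfng was not called without injured 4 (adjusted p = 0.0504). Rfng fell by 0.52 with normexp and quantile normalization and by 0.25 in the authors' deposited table, where the calls of Hes1, Jag1 and Dll1 were lost. The interferon response list had 2 higher and 9 lower of 14 (2 and 9 adjusted over the list alone). Its median was -1.07 (camera adjusted p = 0.0197; adjusted p = 0.398 with an estimated correlation). In the authors' deposited table that median was 0.074 (camera adjusted p = 0.0767). The chemokine Cxcl10 fell by 4.68 ± 0.53, the GTPase Gbp2 was at least 3.33-fold lower (adjusted p = 1.5e-04) and Parp14, an ADP-ribosyltransferase, fell by 1.90. Oas1a, an antiviral synthetase, was at least 2.40-fold higher (adjusted p = 8.5e-04). The antiviral gene Rsad2 rose by 0.59 (adjusted p = 0.0413), a call that needed each of basal 3, basal 4, injured 2, injured 3 and injured 4 (adjusted p 0.0794 to 0.103 without 1 of them). The calls of Gbp2 (-0.74, adjusted p = 0.219), Parp14 (-0.49, adjusted p = 0.516), Oas1a (0.74, adjusted p = 0.122) and Rsad2 (1.5, adjusted p = 0.0868) were lost in the authors' deposited table.

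The oxidative phosphorylation list had 31 higher and 0 lower of 31 members tested (31 and 0 adjusted over the list alone). Its median log2 difference was 1.54 (camera adjusted p = 1.8e-09; adjusted p = 0.398 with an estimated correlation). Sdhd, a subunit of complex II, rose by 2.80 ± 0.27, Cycs, cytochrome c, by 2.72 ± 0.49, and Atp5o, a subunit of ATP synthase, by 2.44 ± 0.26. The proteasome list had 26 higher and 0 lower of 26 (26 and 0 adjusted over the list alone). Its median was 1.64 (camera adjusted p = 6.0e-09; adjusted p = 0.398 with an estimated correlation). Its members included the core subunits Psma6 (2.38) and Psmb7 (2.26) and the regulatory subunit Psmc5 (2.35). The G1/S and DNA replication list had 28 higher and 1 lower of 31 (30 and 1 adjusted over the list alone). Its median was 2.66, or 1.65 to 3.38 over the alternatives (camera adjusted p = 1.7e-06; adjusted p = 0.398 with an estimated correlation). The replication licensing genes Mcm5 and Cdc6 rose by 4.33 ± 0.95 and 4.13 ± 0.63, the initiation factor Mcm10 by 4.30 ± 0.71 and Uhrf1, which maintains DNA methylation, by 3.75 ± 0.60. The replication complex subunit Gins3 fell by 0.55. The G2/M and mitosis list had 26 higher and 0 lower of 26 (26 and 0 adjusted over the list alone). Its median was 3.02, or 1.70 to 3.80 over the alternatives (camera adjusted p = 2.4e-06; adjusted p = 0.398 with an estimated correlation). Among them were Ccna2 (3.79), Cdk1 (3.56) and the kinetochore gene Nuf2, at least 8.31-fold higher (adjusted p = 6.9e-05). The ribosome biogenesis list had 21 higher and 0 lower of 23 (21 and 1 adjusted over the list alone). Its median was 1.71 (camera adjusted p = 6.0e-06; adjusted p = 0.398 with an estimated correlation). Among its members were the pseudouridine synthase Dkc1 (2.61), the nucleolar chaperone Npm1 (2.47) and the helicase Ddx21 (2.26). The glycolysis list had 13 higher and 0 lower of 19 (13 and 1 adjusted over the list alone). Its median was 1.65, or 1.20 with bounds in place of fitted values and 0.85 to 1.78 over the alternatives (camera adjusted p = 0.00302; adjusted p = 0.398 with an estimated correlation). They included the enzymes Pgk1 (3.26), Eno1 (3.04) and Pgam1 (2.85). The embryonic and neonatal sarcomere list had 12 higher and 0 lower of 14 (13 and 0 adjusted over the list alone). Its median was 2.67 (camera adjusted p = 0.00211; adjusted p = 0.410 with an estimated correlation). Ttn, the giant protein of the sarcomere, rose by 4.35 ± 0.97 and the cardiac actin Actc1 by 3.86 ± 0.74, and the troponin Tnnt2 was at least 13.9-fold higher (adjusted p = 4.7e-04). The injured arrays differed on this list, with a median deviation from each gene's mean of 2.00 and 1.86 on injured 3 and 4 against 0.86 and 0.36 on injured 1 and 2. Myog had log2 signals of 3.26 and 3.45 on injured 3 and 4 and of 2.17 and 2.09 on injured 1 and 2. On basal 1 the G2/M and mitosis members had a median deviation of 0.05 from each gene's mean over all arrays, against -1.16 to -2.89 on the other basal arrays and 1.32 to 1.63 on the injured arrays. In the authors' deposited table the calls of Gins3 (-0.28, adjusted p = 0.473), Ccna2 (0.83, adjusted p = 0.202), Sdhd (0.18, adjusted p = 0.827) and Psma6 (0.57, adjusted p = 0.413) were lost.

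**Figure D3:**
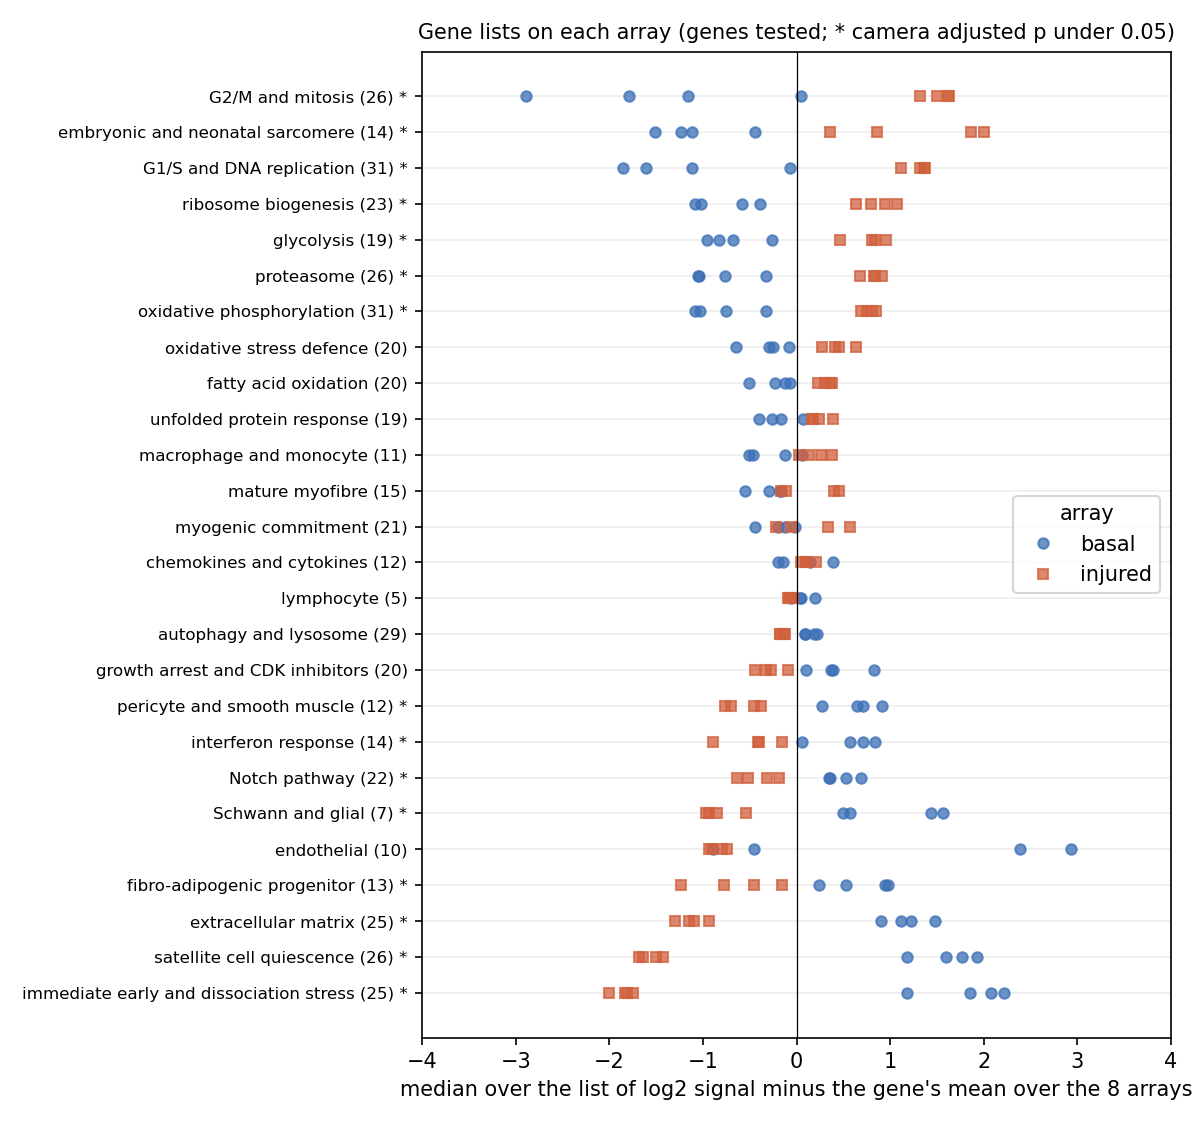
Each line is 1 gene list with the number of members tested, and each point is the median over the list, on 1 array, of the log2 signal minus the gene's mean over the 8 arrays. Blue circles are basal and red squares injured arrays, and a star marks a camera adjusted p under 0.05; the endothelial list stands at 2.94 on basal 1 and 2.39 on basal 2, and at -0.94 to -0.46 on the other arrays.

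Markers of other cell types were also measured. The pericyte and smooth muscle list had 0 higher and 7 lower of 12 members tested (0 and 7 adjusted over the list alone). Its median log2 difference was -1.02, or -0.82 with bounds and -1.19 to -0.37 over the alternatives (camera adjusted p = 6.3e-04; adjusted p = 0.340 with an estimated correlation). Rgs5, a regulator of G protein signalling, was at least 18.2-fold lower (adjusted p = 2.6e-06) and the myosin light chain kinase Mylk at least 9.01-fold lower (adjusted p = 1.2e-04). The channel subunit Abcc9 was at least 7.75-fold (adjusted p = 2.1e-04) and the growth factor receptor Pdgfrb at least 3.78-fold lower (adjusted p = 3.1e-05). On basal 1 and basal 2, 4 of the 12 pericyte members, Rgs5, Mylk, Kcnj8 and Tagln, were higher than on any of the other 6 arrays. The fibro-adipogenic progenitor list had 1 higher and 7 lower of 13 (2 and 7 adjusted over the list alone). Its median was -2.17, or -0.72 with bounds (camera adjusted p = 0.0102; adjusted p = 0.398 with an estimated correlation). The median member was Ly6c1 (adjusted p = 0.120), which was higher on basal 1 and basal 2 than on the other arrays, and the list median was -0.49 without these arrays and -0.29 over genes above background on all arrays. Besides Dcn, the actin-severing protein Gsn and the collagens Col1a1 and Col3a1 fell by 2.74 to 3.13. The 1 higher member, the peptidase Dpep1 (1.54), was called only with all arrays or without basal 4 (adjusted p 0.0544 to 0.100 without any other array). It was -1.13 in the authors' deposited table. The Schwann and glial list had 1 higher and 4 lower of 7 (1 and 4 adjusted over the list alone). Its median was -1.65, or -1.84 to -0.56 over the alternatives (camera adjusted p = 0.0443; adjusted p = 0.398 with an estimated correlation). The call of this list was lost without basal 1 (adjusted p = 0.0695), without injured 2 (adjusted p = 0.0590) and with the replicate block (adjusted p = 0.0523). It was also lost with normexp and quantile normalization (adjusted p = 0.0745), with normexp and the 75th percentile (adjusted p = 0.0584) and with scaling to the median (adjusted p = 0.0539). Its lower members included the membrane protein Pmp22 (-3.27) and the transcription factor Sox10 (-1.65). The receptor Ngfr rose by 0.83 (adjusted p = 0.0334), a call lost without basal 2, basal 3, injured 1, injured 3 or injured 4 (adjusted p 0.0728 to 0.0799). With only genes above background on all arrays, the calls of the interferon response (adjusted p = 0.267), pericyte and smooth muscle (0.111), fibro-adipogenic progenitor (0.111) and Schwann and glial lists (0.267) were lost. The endothelial list was not called, with 1 higher and 2 lower of 10 (0 and 0 adjusted over the list alone). The median was -2.0, or -2.54 to -0.35 over the alternatives (camera adjusted p = 0.105; adjusted p = 0.624 with an estimated correlation). With the preset correlation alone, and never with an estimated one, the list was called without basal 3 (adjusted p = 0.0149) or basal 4 (adjusted p = 0.0352). The same held with all arrays in the authors' deposited table (-0.99, adjusted p = 0.00235) and with no filter on dim probes (-2.10, adjusted p = 0.0298). Its called members were Robo4, at least 4.49-fold lower (adjusted p = 0.0403), Cldn5 (-1.16) and Kdr (0.39). With 1 array left out, Robo4 was called only without basal 3 (adjusted p 0.0633 to 0.0989 otherwise). Cldn5 was not called without basal 2, injured 1, injured 2 or injured 4 (adjusted p 0.0659 to 0.0775), nor Kdr without injured 1, injured 3 or injured 4 (adjusted p 0.0537 to 0.0600). Of the 10 endothelial members, 8 were higher on both basal 1 and basal 2 than on any of the other 6 arrays. The macrophage and monocyte list was not called, with 4 higher and 1 lower of 11 (4 and 0 adjusted over the list alone). The median was 0.45 (camera adjusted p = 0.419). Its called members were Laptm5 (3.97), the protease Ctss, at least 3.88-fold higher (adjusted p = 8.9e-04), the adaptor Tyrobp (1.99; -1.43 in the authors' deposited table), the transcription factor Spi1, at least 2.27-fold higher (adjusted p = 0.00384), and the growth factor receptor Csf1r (-0.30). Csf1r was not called without basal 2, basal 3, basal 4, injured 1, injured 2 or injured 3 (adjusted p 0.0512 to 0.103). It was 0.14 with the mean of its probes and 0.51 in the authors' deposited table. The lymphocyte list was not called, with 1 higher and 1 lower of 5 (0 and 1 adjusted over the list alone). The median was -0.21 (camera adjusted p = 0.564), or 0.069 in the authors' deposited table. Its called members were the kinase Lck (-0.89; 0.51 in the authors' deposited table) and the T cell receptor subunit Cd3e (0.37), which was not called without basal 2, basal 3, injured 1, injured 2 or injured 3 (adjusted p 0.0758 to 0.107). Too few members were above background for a test of the erythroid list (3, none called) and the neutrophil list (3, with Csf3r at -0.61 called). The same held for the tenocyte list (4, with Thbs4, at least 8.89-fold lower, adjusted p = 3.3e-05, Fmod at -1.28 and Scx at 1.36 called). Mylk, Kcnj8, Col1a1, Sox10, Robo4, Cldn5, Kdr, Spi1, Cd3e, Csf3r, Thbs4 and Scx were not called in the authors' deposited table.

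Of the remaining lists, none was called with the main settings, and their members went both ways. The myogenic commitment list had 10 higher and 6 lower of 21 members tested (10 and 6 adjusted over the list alone; camera adjusted p = 0.913). Its median was 0.17, or -0.047 without injured 3 and -0.18 over genes above background on all arrays. The receptor subunit Chrnd (4.29) and the fusion peptide Mymx (4.25) rose with Myog, while Msc (-3.51), a repressor of myogenic factors, and the receptor Megf10 (-2.27) fell. The mature myofibre list had 6 higher and 4 lower of 15 (6 and 4 adjusted over the list alone; camera adjusted p = 0.628). The fast troponin Tnni2 (4.01) and the muscle enolase Eno3 (3.49) rose. Its lower members were the glycogen phosphorylase Pygm (-2.30), Car3 (at least 2.26-fold lower, adjusted p = 0.00594), myoglobin Mb (at least 1.63-fold lower, adjusted p = 0.0114; a log2 difference of 0.042 in the authors' deposited table) and Pvalb (-1.02). The growth arrest and CDK inhibitors list had 7 higher and 10 lower of 20 (7 and 10 adjusted over the list alone; camera adjusted p = 0.105) and a median of -0.38, or 0.14 in the authors' deposited table. It was called over genes above background on all arrays (-1.45, adjusted p = 0.00652) and with no filter on dim probes (-0.64, adjusted p = 0.0414), but in neither case with an estimated correlation. Gas1 (-3.28), Btg1 (-2.28) and Gadd45b (-2.19) fell and the pocket protein Rbl1 (2.04; -0.90 in that table) rose. The autophagy and lysosome list had 5 higher and 13 lower of 29 (5 and 13 adjusted over the list alone; camera adjusted p = 0.0639) and a median of -0.23, or 0.23 in the authors' deposited table. It was called with quantile normalization, with normexp and quantile normalization, with no filter on dim probes, over genes above background on all arrays and with array weights (adjusted p 0.0394 to 0.0498), but in none of these with an estimated correlation. Atg7 (-2.53), Map1lc3a (-2.07) and the kinase Ulk1 (-1.64) fell, and the cathepsins Ctsl (1.89) and Ctsd (0.77; -1.11 in that table), Becn1 (1.19), Bnip3 (1.11) and Wipi1 (0.68) rose. The fatty acid oxidation list had 10 higher and 2 lower of 20 (10 and 2 adjusted over the list alone; camera adjusted p = 0.224), and was called in the authors' deposited table (0.88, adjusted p = 0.0159), but not with an estimated correlation there. Etfb (1.72) and the carrier Slc25a20 (1.57) rose, and Acadvl (-0.64; 0.45 in that table) and the nuclear receptor Ppara (-0.43; 0.43 in that table) fell. Ppara was not called without basal 3, injured 2 or injured 3 (adjusted p 0.0501 to 0.0614). The oxidative stress defence list had 10 higher and 6 lower of 20 (10 and 6 adjusted over the list alone; camera adjusted p = 0.419). Gpx1 (2.55) and Gsr (2.30) rose, and the secreted enzymes Gpx3 (-5.32) and Sod3 (at least 8.45-fold lower, adjusted p = 1.9e-05) fell. The unfolded protein response list had 8 higher and 7 lower of 19 (8 and 7 adjusted over the list alone; camera adjusted p = 0.903). The endoplasmic reticulum proteins Sdf2l1 (2.32) and Creld2 (2.00) rose, and the transcription factor Ddit3 (-2.16) and the chaperone Dnajb9 (-1.82) fell. The chemokines and cytokines list had 3 higher and 3 lower of 12 (3 and 3 adjusted over the list alone; camera adjusted p = 0.812). Its median of 0.15 differed in sign from its mean of -0.21, from its test and from its median of -0.013 without a filter on dim probes. Csf1 (1.90), Il34 (1.48) and Il1b (0.65) rose, and Cxcl1 (-3.44), Lif (at least 2.30-fold lower, adjusted p = 0.00111) and Cx3cl1 (-2.38) fell. Csf1 was not called without basal 3, basal 4, injured 1, injured 2 or injured 3 (adjusted p 0.0624 to 0.0780). Megf10, Car3, Pvalb, Map1lc3a, Ulk1, Dnajb9, Il1b and Lif were not called in the authors' deposited table.

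Beside these groups, Xist, the RNA that coats the inactive X chromosome of female cells, had log2 signals of 3.85, 2.15, -1.12 and -4.97 on basal 1 to 4, and of 1.72, 6.37, 6.55 and 6.57 on injured 1 to 4. All mice were labelled male. Xist differed by 5.32 ± 1.91 (adjusted p = 0.0389), and was not called without basal 3, basal 4, injured 2, injured 3 or injured 4 (adjusted p 0.0717 to 0.0918). The Y-linked helicase Ddx3y was above background on all 4 basal arrays and on injured 1, and Ddx3y, Eif2s3y, Uty and Kdm5d were not above background on injured 2, 3 or 4. With injured 1 as the only injured array, whose spread is then taken to be that of the basal arrays, 756 genes were higher and 997 lower. That fit shares injured 1 and the basal arrays with the calls made with all arrays, so its overlap with them is no separate support. Without basal 1 and basal 2, 4899 genes were higher and 3553 lower. Of these, 4410 and 3085 were among the calls made with all arrays, which rest in part on the same arrays. The interferon response (camera adjusted p = 0.0745) and Schwann and glial lists (camera adjusted p = 0.0745) were no longer called.

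**Figure D4:**
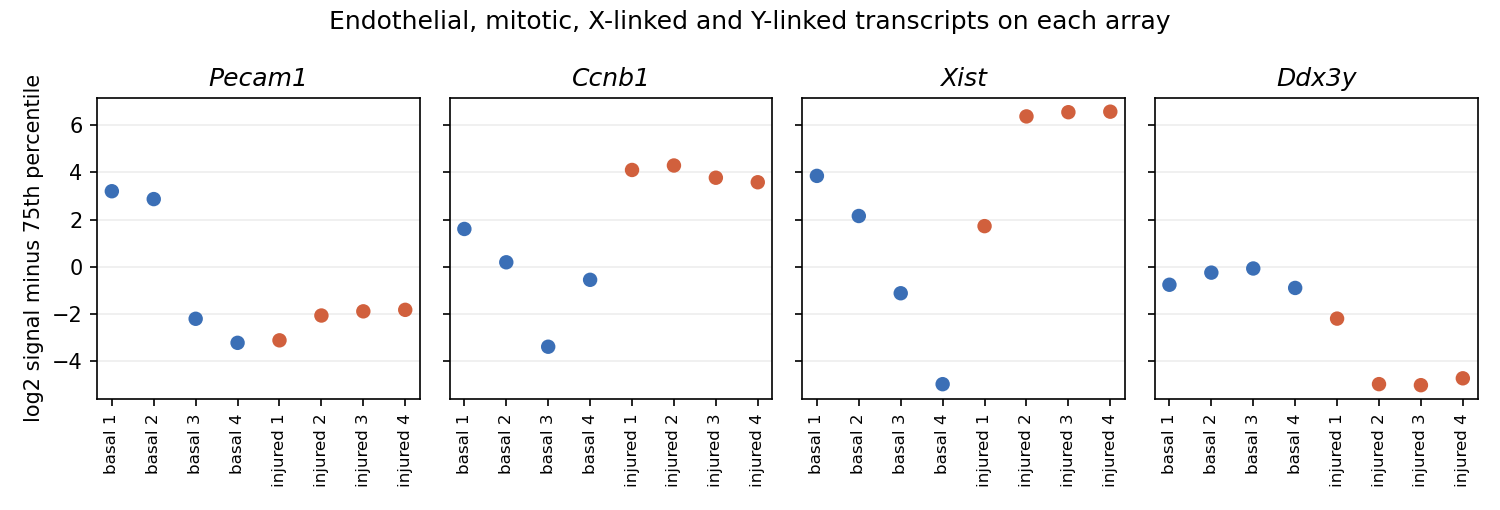
Each panel gives 1 gene, the endothelial Pecam1, the mitotic Ccnb1, the X-linked Xist and the Y-linked Ddx3y, with the log2 signal minus the 75th percentile of each of the 8 arrays on the vertical axis. Xist lies at 6.37 to 6.57 on injured 2, 3 and 4 and at 1.72 on injured 1, and Pecam1 is highest on basal 1 and basal 2.

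All basal arrays lay on 1 slide and all injured arrays on the other, so slide and group cannot be told apart, and no list call held when camera estimated the correlation (2 lists at an unadjusted p under 0.05), while fry called 20 of the 26 lists and other splits of the arrays called up to 14 lists with the preset correlation. That number came from splits that kept most of each group together, and splits with equal numbers of basal and injured arrays on each side called at most 8. The median log2 difference of all genes tested, from which list medians are not corrected, was 0.17, against 0.06 with normexp and quantile normalization and 0.47 in the authors' deposited table, where 81.0% of called genes were higher against 58.8% here.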

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

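The counts over other splits of the arrays were planned, while the tests of the 3 patterns weighed here, the comparisons without several arrays and the values for sex-linked genes, endothelial transcripts and unnamed probes were chosen only after the results were seen.

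The 8 arrays can be split into 4 and 4 in 35 ways, and the real split gave the largest value for each count of genes. That is 1 of the 35 splits, the smallest share that this number of splits can give. Every other split mixes injured with basal arrays, which adds to the spread within its groups. The real split is also the split by slide, so these counts do not tell injury from slide. No other split called any gene (0 at most, against 4823 higher, 3379 lower, and 2790 and 1944 with at least 2-fold change in the real split), although 33 to 2379 genes had an unadjusted limma p under 0.05. The number of lists called was also largest in the real split, but by 1 list only, at 15 against at most 14 in the other splits, with a median of 7.5 and 14 of the 34 other splits at 10 or more lists. Splits without any called gene thus gave nearly as many list calls with the preset correlation, but only where most of each group stayed together. Splits with equal numbers of basal and injured arrays on each side called at most 8 lists. The number of lists does not set the real split apart from splits that keep most of each group together. The counts of members are no separate support, since they come from the same fit, where 60.1% of all genes tested were called. Members of a list are also correlated, with an estimate of 0.75 for the proteasome list.

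A gap between 1 array and the other 3 of its group, large against the group's range, was found in 14 of 322 combinations of a named gene and a group, a rate that chance alone puts at 5%. Of these 14, 3 were on basal and 11 on injured arrays. The sex-linked genes among them were chosen after their values were seen, so the rate cannot be set strictly against 5%. On injured 4, Trp53i11 was at 3.55 (nearest other injured array 3.96), Col1a1 at -1.08 (-3.10), Csf1 at 1.18 (2.01) and Rfng at 2.73 (2.59). On injured 2, Ngfr was at 2.58 (2.89) and Sdf2l1 at 5.61 (5.03), and on injured 3 Ddit3 was at 1.21 (1.09). On basal arrays, Itga7 was at 1.6 on basal 1 (nearest other basal array 1.07), Eif2s3y at -2.66 on basal 1 (-2.04) and Ctsd at 2.41 on basal 3 (2.76). On injured 1, Xist was at 1.72 (nearest other injured array 6.37), Ddx3y at -2.19 (-4.72), Eif2s3y at -2.88 (-4.78) and Uty at -2.77 (-4.68). Of 13502 probes without a gene symbol that were above background, 7111 were called, 3643 higher and 3468 lower; these probes belong to no comparison of named genes.

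Basal 1 and basal 2 lay closer to the injured arrays on the first principal component (-32.9 and -57.6, against -75.3 and -65.1 for basal 3 and 4), and carried endothelial transcripts and Xist. Partial activation of their cells, the biological reading, is argued against for the endothelial transcripts alone, since 9 of 10 endothelial markers were higher on both arrays than on each injured array. RNA or cells of the injured group may be present and stay open, since Xist stood at 20.7% of its injured level on basal 1, where 120 genes at least 16-fold higher in injured arrays than on basal 3 and 4 had a median share of 25.7% (quartiles 18.2% and 34.7%). On basal 2 Xist stood at 6.14% and those genes at a median of 8.62% (5.08% and 13.1%). The 159 genes that were at least 16-fold lower in injured arrays kept a median of 63.1% of their level on basal 1 (quartiles 48.0% and 77.4%), below the 74.3% that a mixture at the median share gives, and 87.4% on basal 2 (70.3% and 111%), below 91.4%. Since the values given by a mixture lie within these quartiles, partial activation as the source of the shift cannot be told apart from mixed RNA or cells. Endothelial cells may also have been present, although the sort removed cells with CD31: 8 of the 10 endothelial markers tested, 0 of them on another list, were higher on both arrays than on the other 6. So were 4 of the 12 pericyte members, Rgs5, Mylk, Kcnj8 and Tagln, 2 of the 4 tenocyte members, Fmod and Thbs4, and at most 4 members of any other list, so cells besides endothelial ones are not ruled out. The transcripts Lrg1 (4.12 and 4.92), Fabp4 (4.95 and 4.82) and Ly6c1 (5.49 and 4.39) were at most 1.22 elsewhere.

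Xist and Y-linked signals differed between arrays labelled male, with Xist high and 0 of 4 Y-linked genes above background on injured 2, 3 and 4. A response of male cells to injury is argued against, since 4 arrays carried Xist or Y-linked signal against their group, namely 3 basal arrays with Xist above background and injured 1 with all 4 Y-linked genes. On injured 2, 3 and 4 Xist lay at 6.37 to 6.57 and Ddx3y at -5.01 to -4.72, against -0.89 to -0.07 for Ddx3y on the basal arrays. These values argue against RNA from male mice alone on injured 2, 3 and 4. RNA from female mice on these arrays cannot be told apart from other sources by escape genes, since 2 of the 3 X-linked genes known to escape inactivation that had signal, Eif2s3x and Kdm5c but not Ddx3x, were higher on each of them than on injured 1, and Kdm6a was not above background on any array. A difference in sex between the groups as the source of the called genes cannot be told apart from injury, since 1 injured array has Y-linked signal: on it, 100% of the 4734 genes called with at least 2-fold change differed from basal 3 and 4 in the called direction, but they had been called with that array included. Called genes made up 60.4% of 447 X-linked genes tested and 60.1% of 13126 autosomal genes.

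The authors' deposited values differed from the scanner values of the same arrays. A normalization of each array on its own would keep the ranks of spots, but Spearman's rho over spots well above background was 0.512 to 0.894. Columns matched to the wrong arrays are argued against, since 8 of the 8 columns deviated from their group mean most like their own array. These correlations were weak, however, at 0.137 for injured 1 to 0.418 for injured 3. The log2 differences of both sources correlated at 0.732 across 10673 genes, and the SD of replicate spots reached 0.326 in the authors' column for basal 4, against 0.114 in its scanner file. Correction steps that act on several arrays together, or values from another scan, stay open and were not tested, and no biological explanation was tested.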

How the results depend on the processing

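The comparisons without basal replicates 1 and 2, without injured replicates 2, 3 and 4 and with unnamed probes were chosen only after the results were seen. Of 109 counts under the alternatives, 94 stayed within 1.5 times the count given in the report. Of 3607 values of named genes and 545 of lists, 3299 and 513 kept their direction and side of the threshold. Lost were 272 gene calls (13 with the sign turned) and 13 list calls (1 with the sign turned), and gained were 18 and 12. Leaving out each array in turn gave 4197 to 4911 higher and 2989 to 3517 lower genes, 2618 to 2990 and 1873 to 2045 with at least 2-fold change, and 14 to 16 lists. The number of lists called was 13 to 18 under all alternatives, and 0 with an estimated correlation under any of them. The replicate block gave 4561 higher and 3194 lower genes.

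Counts with at least 2-fold change moved to 1297 higher and 1099 lower with normexp and quantile normalization and to 1550 and 941 with normexp and the 75th percentile, where the offset of 50 shrinks differences of dim probes. The authors' deposited table gave 774 lower genes, 741 of them at least 2-fold. Genes above background on all arrays gave 1135 lower genes with at least 2-fold change, with fewer genes tested. Without injured replicates 2, 3 and 4, 756 genes were higher and 997 lower, all of them (756 and 997) at least 2-fold, with fewer arrays. With unnamed probes included there were 8421 higher and 6806 lower, 4498 and 4037 at least 2-fold, with more probes tested.

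In the authors' deposited table, 56 named genes lost their call, 12 of them with the sign turned. There the sign turned for the lists autophagy and lysosome (0.23), growth arrest and CDK inhibitors (0.14), interferon response (0.074) and lymphocyte (0.069) and for Dpep1 (-1.13), Tyrobp (-1.43), Csf1r (0.51), Lck (0.51), Rbl1 (-0.90), Acadvl (0.45), Rfng (-0.25), Ctsd (-1.11), Ppara (0.43), Mb (0.042), Eif2s3y (0.28), Ndn (0.53), Igf2 (0.70), Grb10 (-0.47), Nnat (1.14) and Tagln (0.24). Elsewhere it turned for chemokines and cytokines without a filter (-0.013), for myogenic commitment over genes above background on all arrays (-0.18), without injured replicate 3 (-0.047, with -0.047 to 0.36 over all such arrays) and without injured replicates 2, 3 and 4 (-0.28). It also turned for Csf1r with the mean of all probes (0.14), for Rfng with normexp and quantile normalization (-0.52), for Ptprc without basal replicate 4 (0.13, with -0.41 to 0.13 over all such arrays), for Nnat with the mean of all probes (0.17), and for Pecam1 (0.49) and Ly6c1 (0.013) without basal replicates 1 and 2. The near-zero value of Grb10 turned with quantile normalization (-0.18), normexp and quantile normalization (-0.28), normexp and the 75th percentile (-0.066), scaling to the median (-0.030), array weights (-0.048), without injured replicates 2, 3 and 4 (-0.10) and over single arrays left out (-0.088 to 0.24). Where no construction is named, the cause was not tested. A slide block was not run, and signal over background limits what dim probes can show.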

Other observations

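The tests of symbol families and the imprinted and sex-linked genes given here were chosen only after the results were seen. Of 153 families of genes that share the start of their symbol, with at least 10 members each, 14 were called higher and 11 lower (camera with the preset correlation), and 0 with an estimated correlation (6 at an unadjusted p under 0.05). The mitochondrial ribosomal protein genes of the Mrpl family had 42 higher and 0 lower of 47 members (median log2 difference 1.58, adjusted p = 1.2e-07; adjusted p = 0.753 with an estimated correlation), and those of the Mrps family 28 higher and 1 lower of 29 (1.5, adjusted p = 2.0e-05; 0.753). The mitochondrial import genes named Timm had 12 higher and 0 lower of 13 (1.52, adjusted p = 0.00229; 0.753), the nuclear pore genes named Nup 16 higher and 1 lower of 19 (1.34, adjusted p = 0.00455; 0.753), and the cytosolic ribosomal protein genes named Rpl 34 higher and 1 lower of 65 (0.40, adjusted p = 0.0166; 0.870). The Rpl median was 0.16 with quantile normalization, where the median of all genes was 0.13, and 0.15 with normexp and quantile normalization. The lipid transporter genes named Abca had 0 higher and 9 lower of 10 (median -3.21, adjusted p = 2.9e-04; 0.753), with Abca8a at -5.08 ± 0.38 and Abca1, which exports cholesterol, at least 3.26-fold lower (adjusted p = 0.00260). That median was -0.98 with normexp and quantile normalization, -0.87 with normexp and the 75th percentile, -0.88 in the authors' deposited table, where the call of Abca1 was lost (-0.64, adjusted p = 0.125), and -0.63 over genes above background on all arrays. The transcription factor genes named Klf had 2 higher and 8 lower of 12 (-1.19, adjusted p = 0.0236; 0.753), with Klf9 at -5.20, Klf4 at -3.11 and Klf5 at 1.99. In the authors' deposited table the median was -0.20 and the call of Klf4 was lost (-1.46, adjusted p = 0.157). Those named Irf had 0 higher and 7 lower of 11 (-0.95, and 0.09 in the authors' deposited table; adjusted p = 0.0262; 0.753), with Irf8 at least 23.8-fold lower (adjusted p = 1.8e-06) and Irf1 at -2.86, a call lost in that table (-1.67, adjusted p = 0.148). The medians of the other families named here kept their sign under every alternative run.

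Of 16 imprinted genes, of which the cell uses 1 parental copy, 4 were higher, 9 lower and 3 not called. H19 (1.77 ± 0.52, adjusted p = 0.0174), Mest (1.49 ± 0.29, adjusted p = 0.00235) and Peg10 (1.87 ± 0.34, adjusted p = 0.00173) rose with Cdkn1c. Around Meg3 on chromosome 12, which fell by 6.89 ± 0.33 (adjusted p = 3.3e-06), Dlk1 (-1.81), Rtl1 (at least 2.61-fold lower, adjusted p = 2.8e-04) and Mirg (-1.91) fell as well, and Igf2r (-1.59), Plagl1 (-1.16), Peg3 (-1.12), Sgce (-0.82) and Ndn (-0.75) were lower on other chromosomes. Igf2 (-0.81, adjusted p = 0.0512), Nnat (-0.22, adjusted p = 0.434) and Grb10 (0.05, adjusted p = 0.851) were not called, though Igf2 was called under 8 alternatives (-0.59 to -1.55, adjusted p 0.00693 to 0.0401). In the authors' deposited table the calls of Dlk1 (-0.84, adjusted p = 0.367), Rtl1 (-1.77, adjusted p = 0.0979), Plagl1 (-0.78, adjusted p = 0.0815), Peg3 (-0.27, adjusted p = 0.518) and Ndn (0.53, adjusted p = 0.444) were lost. The chromatin protein Hmga1 rose by 3.96 ± 1.00 (adjusted p = 0.00833) beside Hmga2. No explanation was tested for these values.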
